A study of Homo sapiens with 6 samples.

How the data were processed

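RNA sequencing was done on 6 libraries of HTR-8/SVneo, an immortalised cell line derived from human first-trimester extravillous trophoblast, the placental cells that invade the uterine wall. Per the labels, 3 libraries came from cells given an overexpression plasmid for the long noncoding RNA MIR193BHG (OE) and 3 from cells given a mock plasmid (NC), numbered 1 to 3 in each group. The labels do not say that the replicates were separate cultures, so p-values here measure only the spread between these samples, which may be technical.

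The authors deposited a single table of 58302 genes that holds, for each library, a raw count and an FPKM value per gene. Per the series text, the authors aligned the reads to GRCh38 with HISAT2 and tested the genes with edgeR, and the submitters' processing notes name HISAT2, StringTie and edgeR with the build hg38 and no versions. The counting step, its use of strand and its treatment of reads that align to several genes are not given in the sources used here. The library kit is uncertain, because the series text names a stranded, ribosomal RNA depleted total RNA kit and the sample labels name a SMARTER mRNA kit. Reads from overlapping genes, antisense partners, readthrough genes and near-identical copies are therefore treated as impossible to tell apart. The deposited FPKM values were the counts rescaled: over the 18811 genes with a count in every library, 100% of values lay within 1% of the count times a factor per library and gene length, so FPKM adds no measurement of its own. No column belonged to other samples, and 0 rows lacked a gene identifier.

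Total counts per library ran from 13780357 to 15699135, and a row with 0 counts in the shallowest library allows up to 0.218 CPM, taking 3 counts as the floor. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Within each group, the chi-square statistic between pairs of libraries was 39.6 to 103 per degree of freedom over genes with at least 20 counts in the pair, so no library was a second copy of another, and all 6 were kept.

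The counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, the default expression filter, no covariate) in R 4.3.3, which left 15249 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, called at 0.05. The study's own threshold, a log2 difference above 0.5 in size with an unadjusted p under 0.05, was counted in the same fit. Levels are given as TMM-scaled CPM. Single genes were also compared with a two-sided exact permutation test of the group means, for which 3 libraries against 3 cannot give a p below 0.1.

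A set of 28 gene lists was fixed before the data were examined, along with the tests and the alternatives. They cover p53 targets, cell cycle, migration, trophoblast and other cell type markers, stress and inflammatory responses, ribosomal, mitochondrial and noncoding RNA classes, reported miR-193b targets and the genes around the MIR193BHG locus. The oxidative phosphorylation list held 60 symbols for 50 genes, since ATP synthase subunits had been listed under both newer and older names, and all 50 genes were in the table. Lists with at least 3 tested members, 27 of the 28, were tested with limma 3.58.1 camera on log2 CPM (prior count 2), two-sided, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data.

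The rule for named genes, also set beforehand, takes MIR193BHG and TP53, then 12 genes per direction with a mean of at least 5 CPM whose OE and NC libraries do not overlap. They come first from adjusted p under 0.05 by size of change, then from the study's threshold by smallest p. Only MIR193BHG came from the first source, so the others were filled from the second. For each list, up to 4 members with the smallest p are named, called or not, and any gene named outside this rule is said to be so.

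Replicate numbers are shared between groups, so pairing was checked before the fits were compared. The deviations of same-numbered libraries from their group means correlated at 0.466, 0.263 and 0.540 across genes, against −0.437 to −0.064 for libraries with different numbers. Deviations cancel within a group, so positive values for same numbers bring negative ones for different numbers, and this contrast is partly arithmetic. By the preset bound of 0.1 the numbers paired the samples, as read from the data and not from a stated batch. A fit with the replicate number as a block is given beside a result where it changes the call.

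The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-trend on log2(CPM + 1), no expression filter, a mean of at least 5 CPM, edgeR's exact test, the replicate block, and each library left out in turn. Others were added after the data were seen: a per-library correction for exon length and GC content (natural splines with 5 degrees of freedom) from the GENCODE v44 annotation of hg38, the same with the block, DESeq2 with the block, and the block with an estimated correlation. Of the 58302 gene identifiers, 57532 were found in that annotation, all on the same chromosome, and 39675 had identical start and end. Coordinates are those of the deposited table.

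The functions were tested on simulated counts for the OE against NC comparison over 14984 tested genes, with 200 changed genes, 50 for each size. Means were fitted to the real counts by replicate number alone, and dispersions came from the design with the block. Replicate effects were thus built in, which favours the fits with the block. Without the block, edgeR recovered 0% of the 1.5-fold, 2% of the 2-fold, 70% of the 4-fold and 86% of the 8-fold changes with 0 false calls, where DESeq2 recovered 0%, 28%, 86% and 94% with 2 false calls. With the block, edgeR recovered 12%, 68%, 94% and 96% of the same sizes, with 22 false calls among 157, and DESeq2 16%, 70%, 90% and 96%, with 21 among 157. A simulated list of 50 raised genes was called and 0 of 27 unchanged lists were, with independent genes. Figures were drawn with matplotlib 3.10.9.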

Results

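The comparison asked how raised MIR193BHG altered the transcriptome of a trophoblast cell line, in a study whose title concerns proliferation, migration, invasion and p53. Gene counts were available for 3 libraries from HTR-8/SVneo cells given the MIR193BHG plasmid (OE) and 3 from cells given a mock plasmid (NC). The NC libraries held 15699135, 13780357 and 14373387 counts and the OE libraries 14513798, 14720957 and 13799756. Unless stated otherwise, levels are mean ± SD of TMM-scaled CPM over the 3 libraries of a group, and log2 differences are OE minus NC with their standard error.

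MIR193BHG, a long intergenic noncoding RNA (ENSG00000262454, GRCh38 chromosome 16, 14301389 to 14331067, plus strand), was low in mock cells and far higher in every OE library. Its counts were 11, 15 and 20 in NC replicates 1, 2 and 3 and 543, 370 and 233 in OE replicates 1, 2 and 3. The level went from 1.06 ± 0.332 to 26.9 ± 11.7 CPM, a log2 difference of 4.66 ± 0.43 or 25.3-fold, with an edgeR adjusted p of 0.0374. The fold within replicate numbers was 46.5, 20.2 and 10.99. The gene spans the microRNA genes MIR193B (14303967 to 14304049) and MIR365A (14309285 to 14309371), neither of which overlapped an annotated exon of it, and both of which had 0 counts in all 6 libraries. Mature microRNAs are too short to be read by libraries of this type, and counts do not separate plasmid from chromosomal transcripts. With the replicate block the log2 difference was 4.58 and the adjusted p 0.0834. The call was also lost without NC replicate 1, 2 or 3 (adjusted p = 0.252, 0.331 and 0.0602) and without OE replicate 1 or 2 (0.0546 and 0.224), although the log2 difference stayed between 4.27 and 4.90 whichever library was left out.

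**Figure D1:**
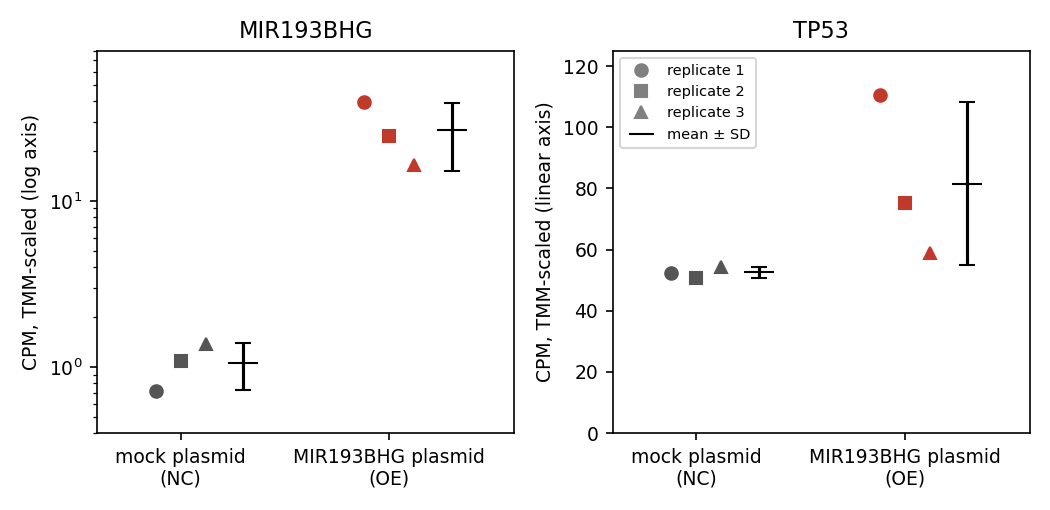
MIR193BHG (left, log axis) and TP53 (right, linear axis) in TMM-scaled CPM for each NC and OE library, with the replicate number as the symbol and bars for the mean ± SD of 3 libraries. MIR193BHG lies between 0.714 and 1.38 CPM in NC and between 16.5 and 39.5 CPM in OE, and TP53 between 50.8 and 54.3 CPM in NC and between 58.8 and 110.7 CPM in OE.

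MIR193BHG was the 1 gene that passed the adjusted threshold of 15249 tested, with 1 higher and 0 lower by edgeR. An unadjusted p under 0.05 was found for 206 genes, where chance alone would give 762 if the libraries were unpaired. Past the study's unadjusted threshold lay 169 genes, 66 higher and 103 lower in OE. After the length and GC correction the split was 76 higher and 70 lower. In 930 genes, 6.10%, the libraries of the groups did not overlap, where chance would give 10% for unpaired libraries. Same-numbered libraries were alike, so both chance values are too high for these data. Other splits of the 6 libraries that part every same-numbered pair gave 127, 127 and 314 genes at an unadjusted p under 0.05 without the block. With the replicate block edgeR called 0 genes (851 at unadjusted p under 0.05) and placed 425 past the study's threshold, 176 higher and 249 lower. Limma called 1 gene and DESeq2 called 8, or 26 with the block.

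The 8 genes called by DESeq2, named after their values were seen, were MIR193BHG, SMC1A, AC134772.2 and a noncoding row that the table names ZNF503 on the higher side, and UPK3BL1, PRR13, ATRIP and AC020688.1 on the lower. SMC1A encodes a core subunit of cohesin, the ring that holds sister chromatids together, and rose from 126 ± 13.4 to 229.7 ± 15.73 CPM (log2 0.86 ± 0.18, DESeq2 adjusted p = 0.0420, edgeR 1.00). PRR13 (chromosome 12, 53441605 to 53446645) fell from 93.8 ± 14.5 to 41.2 ± 2.53 CPM (log2 −1.19 ± 0.19, DESeq2 adjusted p = 0.000511, edgeR 0.733). ATRIP encodes the partner of the checkpoint kinase ATR and fell from 19.3 ± 4.37 to 5.84 ± 2.78 CPM (DESeq2 adjusted p = 0.0420), while AC134772.2 rose from 5.17 ± 1.21 to 12.5 ± 1.45 CPM (0.0445). These genes cover nearly the same stretch of chromosome 3 (48446710 to 48465716 and 48446846 to 48467645), so their reads may not be separable. Their summed level was 24.4 ± 4.85 CPM in NC and 18.3 ± 3.12 CPM in OE, lower in OE in each of the 3 pairs (exact permutation p = 0.2, where 0.1 is the smallest possible). The ZNF503-named row (ENSG00000270087, chromosome 10, 75279726 to 75401246) had 0 counts in each NC library and 15, 13 and 11 in OE, and it overlaps the protein-coding ZNF503. With the block DESeq2 no longer called this row, while the others of the 8 were still called. The pseudogene AC020688.1 had 23, 19 and 14 counts in NC and 0 in each OE library. UPK3BL1 had 192, 163 and 14 counts in NC and 1 in each OE library, and it overlaps other annotated genes. Exons of SMC1A, PRR13 and AC020688.1 also overlap those of other annotated genes, whose reads the counts may not separate.

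The other named genes met only the study's unadjusted threshold. On the higher side, HACD3, an enzyme of very long chain fatty acid elongation, averaged 60.2 ± 4.19 in NC and 122 ± 38.0 CPM in OE. VCL, which encodes the focal adhesion protein vinculin, averaged 99.03 ± 14.8 and 184 ± 63.7 CPM. CCNC, cyclin C of the Mediator kinase module, averaged 28.8 ± 5.99 and 50.4 ± 4.09 CPM, RPRD1B, an RNA polymerase II binding protein, 25.9 ± 5.84 and 51.0 ± 13.1 CPM, TADA2B 14.7 ± 4.52 and 27.8 ± 3.19 CPM and AFF1 9.88 ± 1.58 and 18.9 ± 4.95 CPM. UXS1 averaged 32.8 ± 0.240 and 52.1 ± 1.28 CPM, and SETMAR, LYRM1 and CAPRIN2 had log2 differences of 1.19, 1.17 and 0.72. On the lower side, MZT2B, a component of the gamma-tubulin ring complex, averaged 173 ± 15.0 in NC and 103 ± 21.4 CPM in OE, and NUBP2, a cytosolic iron-sulfur assembly factor, 90.4 ± 27.1 and 46.4 ± 11.5 CPM. NIP7, a ribosome biogenesis factor, averaged 62.9 ± 6.97 and 42.2 ± 1.31 CPM, and GET4, which acts in tail-anchored protein insertion, 79.6 ± 15.1 and 50.8 ± 3.75 CPM. DEXI, MCRIP1, DNLZ, RBM14-RBM4, DNPH1 and NT5C had log2 differences from −1.13 to −0.61. RBM14-RBM4 is a readthrough gene that shares exons with RBM14 and RBM4. With edgeR each gene of this paragraph had an adjusted p of 1.00, or 0.815 with the block. With DESeq2 and the block, HACD3, CCNC, RPRD1B, LYRM1, MZT2B, NUBP2 and DEXI passed, at adjusted p from 0.00338 to 0.0430.

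TP53, the gene of the tumour suppressor p53 (ENSG00000141510, chromosome 17, 7661779 to 7687550), lay higher in each OE library than in any NC library without passing the adjusted threshold. It averaged 52.5 ± 1.73 CPM in NC and 81.6 ± 26.5 CPM in OE, a log2 difference of 0.64 ± 0.24 (edgeR unadjusted p = 0.0289, adjusted p = 1.00, exact permutation p = 0.1, the smallest possible). The ratio within replicate numbers was 2.11, 1.48 and 1.08. Without OE replicate 1 the log2 difference was 0.35. TP53 overlaps the antisense gene WRAP53, which averaged 92.5 ± 9.24 and 87.6 ± 14.6 CPM, and the counts cannot be assigned to a strand with certainty.

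The p53 target list did not pass its test: of 39 tested members 18 were higher and 21 lower, with a median log2 difference of −0.02 (camera adjusted p = 0.761). The median turned to 0.03 without NC replicate 2, 0.11 without NC replicate 3 and 0.12 without OE replicate 1. CDKN1A, which encodes the cell cycle inhibitor p21 and was named here for its standing as a p53 target, averaged 505 ± 176 CPM in NC and 405 ± 174 CPM in OE, with ratios of 0.695, 0.761 and 0.895 within replicate numbers (exact permutation p = 0.5, edgeR unadjusted p = 0.0230 with the block, adjusted p = 0.815). MDM2, whose product degrades p53, averaged 218 ± 20.2 and 233 ± 88.5 CPM, with ratios of 0.671, 1.24 and 1.24 (exact permutation p = 1). The member with the smallest p was BBC3, the proapoptotic gene also called PUMA, at 13.9 ± 3.77 and 7.56 ± 2.07 CPM (log2 −0.88 ± 0.31, edgeR unadjusted p = 0.0193, adjusted p = 1.00). CCNG1 averaged 36.3 ± 4.04 and 48.1 ± 4.37 CPM, PMAIP1 73.4 ± 21.1 and 53.8 ± 7.99 CPM, and APAF1 27.4 ± 5.64 and 36.9 ± 7.25 CPM. Among the apoptosis regulators 10 of 24 were higher and 14 lower (median −0.05, adjusted p = 0.471), with BAD at 63.6 ± 11.8 and 50.4 ± 2.12 CPM and BAK1 at 87.1 ± 13.5 and 72.4 ± 2.75 CPM. This list joins genes that promote apoptosis with genes that oppose it, so opposite shifts would cancel in its median and its test.

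Over all 28 lists and 640 tested memberships, edgeR called 0 members, both over all genes tested and adjusted over the list alone, with 9 memberships at an unadjusted p under 0.05. DESeq2 called 0 over all genes and 2 adjusted over the list alone, both of them the keratin gene KRT7, which stands in a pair of lists. With the block 76 memberships had an unadjusted p under 0.05, edgeR called MKI67, SDC1, KRT7 and RN7SL2 adjusted over the list alone, and DESeq2 called MKI67, SDC1 and HSPA8 over all genes. As whole lists, 7 passed camera with the preset correlation, 2 shifted upward and 5 downward. With an estimated correlation 0 passed, with a smallest adjusted p of 0.597 and a smallest unadjusted p of 0.0643.

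Cell cycle genes of mitosis stood higher in OE as a list, and those of replication did not pass the test. In the G2/M and mitosis list 30 of 39 members were higher and 9 lower, with a median log2 difference of 0.13 (camera adjusted p = 0.0083, and adjusted p = 0.833 with an estimated correlation). MKI67, the proliferation marker Ki-67, averaged 45.7 ± 19.4 CPM in NC and 87.2 ± 48.3 CPM in OE, with ratios of 2.08, 1.91 and 1.51 within replicate numbers (edgeR unadjusted p = 0.0624). With the block MKI67 passed by DESeq2 over all genes (adjusted p = 0.00653) and by edgeR over the list alone (0.0218), with edgeR over all genes at 0.815. NUSAP1, a spindle protein, averaged 76.5 ± 25.8 and 103 ± 14.3 CPM, KIF23 159 ± 26.5 and 198 ± 27.2 CPM, and the phosphatase gene CDC25C 24.5 ± 2.61 and 31.0 ± 5.59 CPM. In the G1/S and DNA replication list 19 of 36 were higher and 17 lower, with a median of 0.02, a mean of 0.00041 and a camera direction of down (adjusted p = 0.866). That median turned to −0.00061 without NC replicate 3, −0.08 without OE replicate 2, −0.0035 without OE replicate 3 and −0.01 after the length and GC correction. CDT1, a replication licensing factor, averaged 220.1 ± 5.38 and 179.8 ± 14.4 CPM and E2F1 54.2 ± 10.2 and 45.7 ± 5.09 CPM. The 14 tested replication-dependent histone genes had a median of −0.06 (adjusted p = 0.306), with HIST1H1C at 236 ± 14.3 and 214 ± 16.1 CPM. The mitosis median was 0.33 without NC replicate 1 and 0.24 without OE replicate 2. The mitosis call was lost without NC replicate 2 (median −0.00045), NC replicate 3 (0.08) or OE replicate 1 (−0.01), and without the expression filter (adjusted p = 0.0592).

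**Figure D2:**
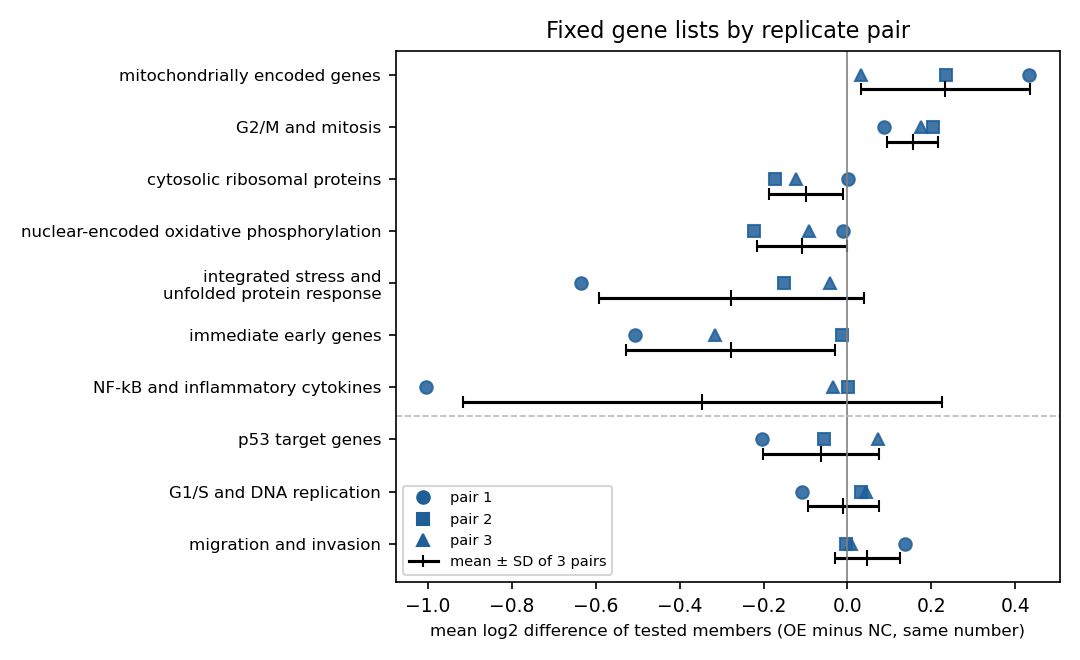
Mean log2 difference (OE minus NC) of the tested members of a list within each replicate number (symbols), with bars for the mean ± SD of the 3 pairs. The 7 lists above the dashed line passed camera with the preset correlation, and the 3 below it did not. The NF-kB list has a pair mean of −1.005 in pair 1 and 0.0012 and −0.03 in pairs 2 and 3.

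Genes of migration and invasion did not pass as a list, with 22 of 35 members higher, 13 lower and a median of 0.02 (camera adjusted p = 0.425). MET, the receptor for hepatocyte growth factor, averaged 65.3 ± 1.18 CPM in NC and 87.4 ± 5.95 CPM in OE (log2 0.42 ± 0.16, edgeR unadjusted p = 0.0304, adjusted p = 1.00). PTK2, focal adhesion kinase, averaged 184 ± 30.6 and 233 ± 52.1 CPM, and the integrin genes ITGAV 69.9 ± 2.05 and 82.5 ± 8.28 CPM and ITGA1 9.54 ± 1.24 and 11.8 ± 1.40 CPM. Of the epithelial and mesenchymal genes 13 of 20 were higher (median 0.10, adjusted p = 0.761), with ZEB1 at 8.99 ± 1.04 and 11.6 ± 3.63 CPM. That list joins markers of both states, so opposite shifts would cancel in its median and its test. KRT7, a keratin of simple epithelia, averaged 5.75 ± 1.59 and 2.56 ± 0.272 CPM (log2 −1.17 ± 0.32, edgeR unadjusted p = 0.0057), and with the block passed by edgeR over the cytotrophoblast list alone (adjusted p = 0.0452). Collagens and matrix genes had 15 of 23 members higher (median 0.10, adjusted p = 0.123), with FBN2 at 82.9 ± 17.3 and 107.7 ± 19.6 CPM, and the TGF-beta response list had 12 of 20 higher (median 0.05, adjusted p = 0.901), with SMAD6 at 1.47 ± 0.464 and 2.71 ± 1.64 CPM. The migration list passed without NC replicate 2 (median 0.19, adjusted p = 0.0122) or OE replicate 3 (0.21, 0.0024), while its median turned to −0.09 without NC replicate 3, −0.02 without OE replicate 1 and −0.05 without OE replicate 2. With all 6 libraries its adjusted p was 0.921 with an estimated correlation. The collagen list passed with the replicate block (adjusted p = 0.0391, but 0.742 with an estimated correlation) or without NC replicate 2 (median 0.21, adjusted p = 0.000304), while its median turned to −0.08 without NC replicate 1. Its pair means were 0.51, −0.05 and −0.07, so only pair 1 was shifted upward.

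None of the 3 trophoblast marker lists passed. Of the cytotrophoblast and stem cell markers 6 of 12 tested members were higher (median −0.07, adjusted p = 0.327), with the imprinted gene PEG10 at 16.7 ± 3.43 CPM in NC and 33.8 ± 22.2 CPM in OE and the transcription factor gene GATA3 at 28.6 ± 4.50 and 20.4 ± 5.04 CPM. Of the syncytiotrophoblast markers 3 of 9 were higher (median −0.09, adjusted p = 0.586), and SDC1, the cell surface proteoglycan syndecan-1, averaged 241 ± 66.7 and 139 ± 50.4 CPM (edgeR unadjusted p = 0.0272). With the block SDC1 passed by DESeq2 over all genes (adjusted p = 0.00517) and by edgeR over the list alone (0.0062), lower in OE in each of the 3 pairs. Of the extravillous markers 6 of 11 were higher (median 0.06, adjusted p = 0.440), with MMP11 at 4.39 ± 0.846 and 5.77 ± 1.45 CPM. Several classical markers had 0 counts in all 6 libraries, among them HLA-G, ASCL2, ELF5, CDX2 and GCM1, chosen here after their values were seen. Such genes made up 4 of 20 cytotrophoblast and stem cell, 8 of 25 syncytiotrophoblast and 6 of 24 extravillous markers, so most markers of each list had counts.

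Among markers of other cell types, the stromal list passed under some settings and the endothelial list under none of those run. Of 16 leukocyte markers, 14 were below the expression filter, and the remaining genes CD68 and CORO1A, which are not specific to leukocytes, averaged 78.0 ± 23.2 and 57.0 ± 19.7 CPM and 16.2 ± 5.56 and 13.4 ± 6.36 CPM. Of the endothelial markers 0 of 4 tested members were higher (median −0.16, adjusted p = 0.258), with 0 at an unadjusted p under 0.05 by edgeR and 0 called by DESeq2, and EGFL7 at 58.7 ± 9.02 and 46.7 ± 9.38 CPM. Of the stromal markers 7 of 7 were higher (median 0.30, adjusted p = 0.0666), with NT5E at 43.6 ± 8.16 and 53.7 ± 5.72 CPM and THY1 at 32.6 ± 5.88 and 42.2 ± 20.6 CPM. The stromal list passed with the replicate block (adjusted p = 0.0204, but 0.673 with an estimated correlation), with limma-trend (0.0479), after the length and GC correction (0.0217), and without NC replicate 2 (median 0.29) or OE replicate 3 (0.34). Its adjusted p was 0.833 with an estimated correlation. Its median was 0.15 without NC replicate 3 and 0.06 without OE replicate 1. Its pair means were 0.70, 0.21 and −0.03.

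Inflammatory, stress and immediate early genes stood lower in OE as lists. The mean log2 differences of pairs 1, 2 and 3 were −1.005, 0.0012 and −0.03 for NF-kB, −0.64, −0.15 and −0.04 for the integrated stress list and −0.51, −0.01 and −0.32 for the immediate early genes. In the NF-kB and inflammatory cytokine list 3 of 22 members were higher and 19 lower, with a median of −0.12 (camera adjusted p = 0.0048, and adjusted p = 0.597 with an estimated correlation). The cytokine gene IL11 averaged 249 ± 42.7 and 183 ± 32.6 CPM, CXCL3 49.1 ± 27.1 and 29.7 ± 6.46 CPM, and NFKB2 247 ± 37.3 and 192 ± 20.1 CPM. In the integrated stress and unfolded protein response list 9 of 31 were higher and 22 lower (median −0.20, adjusted p = 0.0048, or 0.597 with an estimated correlation), with CEBPB at 458 ± 84.6 and 325 ± 21.2 CPM, DDIT4 at 391 ± 174 and 236 ± 26.8 CPM and CHAC1 at 99.6 ± 7.78 and 52.3 ± 32.4 CPM. The first 2 of these had edgeR unadjusted p of 0.0367 and 0.0416. Of the immediate early genes 4 of 24 were higher and 20 lower (median −0.23, adjusted p = 0.0048, or 0.597 with an estimated correlation), with the phosphatase gene DUSP1 at 667 ± 199 and 451 ± 108 CPM and KLF6 at 140.0 ± 72.8 and 79.8 ± 41.4 CPM. The NF-kB median was −0.28 with limma-trend, −0.31 with the block, −0.20 after the length and GC correction and −0.19 to −0.38 with a library left out. That of integrated stress was −0.08 without NC replicate 3 and −0.37 without OE replicate 3. All 3 calls were lost without NC replicate 1 (medians −0.19, −0.11 and −0.18), the first 2 also without OE replicate 1 (−0.25 and −0.03), and the immediate early call after the length and GC correction (median −0.14, adjusted p = 0.106).

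Transcripts of the mitochondrial genome stood higher in OE as a list, whereas nuclear genes of the respiratory chain and the ribosome stood lower, though not evenly over the pairs. The mean log2 differences of pairs 1, 2 and 3 were 0.43, 0.23 and 0.03 for the mitochondrial genes. They were −0.01, −0.22 and −0.09 for oxidative phosphorylation and 0.0003, −0.17 and −0.12 for ribosomal proteins. Of the 13 mitochondrially encoded genes 12 were higher, with a median of 0.22 (camera adjusted p = 0.0018, and adjusted p = 0.597 with an estimated correlation). MT-ND4L averaged 608 ± 96.7 and 797 ± 71.4 CPM, MT-ATP8 435 ± 50.1 and 559 ± 63.4 CPM, and MT-ND2 1368 ± 70.0 and 1802 ± 456 CPM. Mitochondrially encoded genes took 2.46%, 2.99% and 3.57% of the counts in NC replicates 1, 2 and 3 and 3.13%, 3.69% and 3.69% in OE. Mitochondrial ribosomal RNA took 0.511%, 0.463% and 0.840% in NC and 0.606%, 0.630% and 1.03% in OE. In the oxidative phosphorylation list 13 of 50 were higher and 37 lower (median −0.08, adjusted p = 0.0225, or 0.873 with an estimated correlation), with CYC1 at 244 ± 11.3 and 189.6 ± 27.2 CPM and COX5B at 185 ± 37.4 and 137 ± 36.8 CPM. Of the cytosolic ribosomal protein genes 18 of 73 were higher and 55 lower (median −0.06, adjusted p = 0.0225, or 0.833 with an estimated correlation), with RPL8 at 1586 ± 19.7 and 1225 ± 191 CPM and RPL29 at 566 ± 309 and 319 ± 89.1 CPM. Ribosomal proteins have many processed pseudogenes, whose reads may be shared. Over the 14298 tested genes with annotated exons and a mean of at least 1 CPM, the median log2 difference was −0.09 in the quintile with the shortest exons and 0.10 in that with the longest, and 0.11 at the lowest GC content and −0.14 at the highest. The oxidative phosphorylation median was −0.14 without NC replicate 2, −0.16 without NC replicate 3 and −0.27 without OE replicate 1. The ribosomal median was −0.14 without NC replicate 2 and −0.19 without OE replicate 1. The mitochondrial call was lost without NC replicate 1 (adjusted p = 0.1252), although its median stayed between 0.19 and 0.32 whichever library was left out. The oxidative phosphorylation call was lost without NC replicate 1 (median 0.05), OE replicate 2 (−0.01) or OE replicate 3 (−0.03). The ribosomal call was lost without NC replicate 1 (0.03), NC replicate 3 (−0.08), OE replicate 2 (0.02) or OE replicate 3 (−0.09). It was also lost after the length and GC correction (median −0.07, adjusted p = 0.0582).

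Of the remaining lists, the heat shock genes had 16 of 19 members higher and a median of 0.23 (adjusted p = 0.0605). HSPA8, a constitutive Hsp70 chaperone gene, averaged 358 ± 236 CPM in NC and 834 ± 876 CPM in OE and HSPA1A 61.8 ± 23.6 and 211 ± 296 CPM. In replicates 1, 2 and 3 HSPA8 stood at 629, 240.1 and 204 CPM in NC and 1845, 338 and 318 CPM in OE, and HSPA1A at 89.0, 49.8 and 46.7 CPM in NC and 552, 34.7 and 45.6 CPM in OE. With the block HSPA8 passed by DESeq2 over all genes (adjusted p = 0.0407) but not by edgeR (0.815, or 0.0796 over the list alone). The heat shock list passed with the replicate block (adjusted p = 0.0013, but 0.673 with an estimated correlation), with limma-trend (0.0432), and without NC replicate 1 (median 0.54), OE replicate 2 (0.31) or OE replicate 3 (0.36), while its median turned to −0.19 without OE replicate 1. The hypoxia and glycolysis list had 17 of 31 higher (median 0.01, adjusted p = 0.961), with BNIP3L at 67.8 ± 7.95 and 91.7 ± 19.8 CPM, and cholesterol biosynthesis 15 of 24 (median 0.03, adjusted p = 0.539), with HMGCR at 23.1 ± 0.645 and 28.4 ± 2.86 CPM. The cholesterol list passed without OE replicate 3 (median 0.19, adjusted p = 0.0385). With all 6 libraries its adjusted p was 0.921 with an estimated correlation. Of the nuclear and abundant noncoding RNAs 5 of 14 were higher (median −0.14, adjusted p = 0.996), with MALAT1 at 144 ± 57.5 and 221 ± 25.1 CPM and RN7SL2 at 17.0 ± 6.58 and 8.64 ± 1.86 CPM, the latter passing by edgeR with the block over the list alone (adjusted p = 0.0314).

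Because MIR193BHG hosts microRNA genes, reported miR-193b targets and genomic neighbours were examined. Of the reported targets 8 of 10 were higher (median 0.13, or 0.05 to 0.28 with a library left out, pair means −0.02, 0.24 and 0.11, adjusted p = 0.123), with NF1 at 79.98 ± 12.2 and 108.2 ± 18.5 CPM, STMN1 at 254 ± 28.3 and 324 ± 39.8 CPM and CCND1 at 217 ± 67.6 and 261 ± 109 CPM. Of 8 tested neighbours on chromosome 16, 6 were higher (median 0.09, adjusted p = 0.327). The DNA repair nuclease gene ERCC4 averaged 18.8 ± 5.88 and 28.6 ± 7.39 CPM, PARN 68.9 ± 8.58 and 80.05 ± 2.68 CPM, NTAN1 38.0 ± 3.78 and 35.1 ± 4.33 CPM and CPPED1 50.5 ± 8.06 and 54.9 ± 11.9 CPM. MRTFB averaged 18.8 ± 3.72 and 20.4 ± 7.22 CPM, RRN3 118.6 ± 22.6 and 123.2 ± 39.3 CPM, NOMO1 145 ± 58.0 and 149.7 ± 41.8 CPM and BFAR 76.5 ± 12.4 and 76.2 ± 9.61 CPM, with NOMO1 and RRN3 having near-identical copies nearby.

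Replicate number separated the libraries more than the plasmid did. The first principal component of log2 CPM held 45.4% of the variance and placed replicate 1 of both groups at the negative end (−36.7 and −53.7) and replicate 3 at the positive end (39.1 and 40.5). Component 4, with 13.0% of the variance, was the first to separate the groups, at −18.9 to −16.1 in NC and 11.9 to 29.5 in OE. The type I interferon list did not pass, with 13 of 26 members higher and 13 lower in OE (median 0.03, camera adjusted p = 0.901). IFIT2, an interferon-induced antiviral gene, stood at 43.7, 1.16 and 2.13 CPM in NC replicates 1, 2 and 3 and at 27.4, 0.597 and 2.98 CPM in OE. IRF7 averaged 44.2 ± 25.6 and 37.8 ± 23.3 CPM, MX1 6.14 ± 0.818 and 5.33 ± 0.864 CPM, and STAT2 53.8 ± 17.0 and 64.9 ± 35.8 CPM. The median of this list was 1.40 without NC replicate 1, −0.39 without NC replicate 2, −1.44 without OE replicate 1 and 0.38 without OE replicate 2, each past the test with the preset correlation. These fits had no block, so the same-numbered partner of the library left out stayed in, and replicate number enters the difference. The pair means with all 6 libraries were −0.05, 0.10 and 0.23. With an estimated correlation and all 6 libraries the list had an adjusted p of 0.996.

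**Figure D3:**
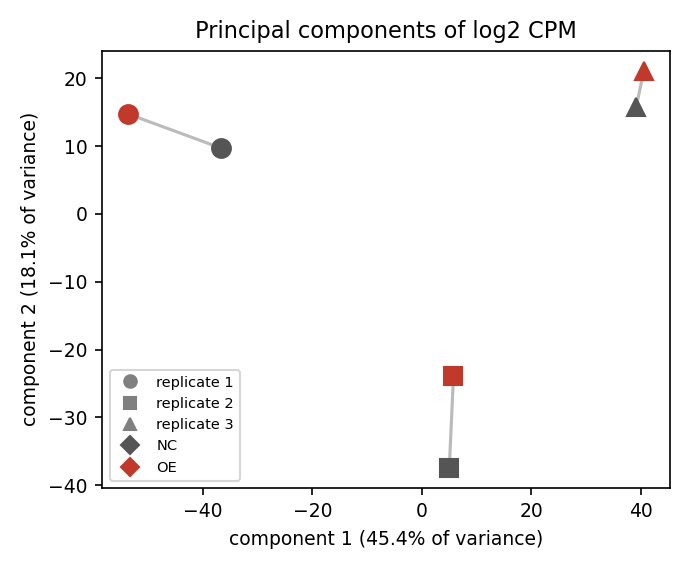
Principal components 1 and 2 of log2 CPM for the 6 libraries, coloured by group, with the replicate number as the symbol and grey lines joining same-numbered libraries. Replicate 2 of both groups lies at −37.5 and −23.9 on component 2, where the other 4 libraries lie between 9.72 and 21.1.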

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

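Of 156 values that the alternatives gave for the main results, 105 kept their direction and their side of the threshold, or for counts stayed within 1.5 times, and 13 reversed. RLE and upper-quartile scaling and the filter at a mean of 5 CPM changed none of the calls, and the median log2 difference of all tested genes was 0.0139 with TMM, 0.0129 with RLE and 0.0274 with upper-quartile scaling. The length and GC correction and the DESeq2 and correlation variants of the block were chosen after the data were seen. The number of genes called, 1 with edgeR, was 8 with DESeq2, 26 with DESeq2 and the replicate block, and 0 to 4 with a library left out. It was 0 without a filter (481 genes at unadjusted p under 0.05, with 31180 tested), 0 with the length and GC correction (163) and 0 with that correction and the block (799), all in edgeR. The gene called without NC replicate 3 was UPK3BL1, and the 4 without OE replicate 3 were MIR193BHG, ZNF48, AC018521.1 and CDK5RAP3, named after their values were seen. The 169 genes past the study's threshold became 449 without a filter, 331 with the length and GC correction and the block, 303 with DESeq2 and the block, 1 with an adjusted p in its place, and 158 to 421 with a library left out (329 without NC replicate 1, 257 without NC replicate 3, 421 without OE replicate 1, 314 without OE replicate 3). The log2 difference of MIR193BHG was 4.65 without a filter, 4.63 with the length and GC correction, 4.53 with that and the block, and 4.27 to 4.90 with a library left out, without passing except without OE replicate 3. Over its 16 alternatives the adjusted p ran from 7.39e-25 to 0.351.

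The replicate block, the paired fit, turned the edgeR call of MIR193BHG (4.58, adjusted p = 0.0834), so 0 genes were called (851 at unadjusted p under 0.05, and 26 by DESeq2 with the same block), and placed 425 genes past the study's threshold. It raised the lists called from 7 to 10, adding collagens, stromal markers and heat shock, and changed no other call besides those of list members named in the report. The number of lists called was 0 with an estimated correlation, 0 with that and the block, and 3 to 10 with a library left out (3 without NC replicate 1). The median of the G2/M and mitosis list lost its call without a filter (0.12), with the estimated correlation (0.13, and 0.13 with the block), and ranged from −0.0125 to 0.33 with a library left out. That of migration and invasion ranged from −0.0887 to 0.21, passing without NC replicate 2 (0.19) or OE replicate 3 (0.21). With a library left out the median of 17 lists reversed: besides those of mitosis and migration, p53 targets (−0.14 to 0.12), G1/S (−0.0792 to 0.0533), oxidative phosphorylation (−0.27 to 0.0512), ribosomal proteins (−0.19 to 0.0337), type I interferon (−1.44 to 1.40), heat shock (−0.19 to 0.54), collagens (−0.0780 to 0.21), epithelial and mesenchymal state (−0.0633 to 0.25), syncytiotrophoblast (−0.23 to 0.10) and extravillous markers (−0.0417 to 0.0952), apoptosis (−0.18 to 0.0664), hypoxia (−0.19 to 0.12), cholesterol (−0.0844 to 0.19), TGF-beta (−0.12 to 0.10) and noncoding RNAs (−0.21 to 0.11). Other settings reversed G1/S (−0.0121 with the length and GC correction, −0.0227 with that and the block), cytotrophoblast markers (0.0452 and 0.0206, and 0.00114 at a mean of 5 CPM), histones (0.00636 and 0.000201), hypoxia (−0.00137 at a mean of 5 CPM) and interferon (−0.0454 without a filter). Of these 44 reversed values 2 passed the test, both of interferon. Lists other than p53 targets, G1/S, mitosis and migration kept 338 values, with 20 now called and 25 no longer called, and the named genes kept 355, with 13 now called. The fits with a library left out had no block, so the same-numbered library of the other group stayed in without its pair. A difference between replicate numbers then enters the group difference, and these ranges do not measure the plasmid effect alone. Beyond this, the cause of these changes was not tested. In the simulation, which had replicate effects built in, edgeR recovered 2% of 2-fold changes without the block and 68% with it. False calls were 0 of 79 and 22 of 157. At the depth of the shallowest library a gene with 0 counts may lie at up to 0.218 CPM.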

Other observations

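The genes of this paragraph were picked after their values were seen, and no test of replicate number against plasmid was run on them. IFIT1 stood at 100.8, 0.144 and 2.06 CPM in NC replicates 1, 2 and 3 and at 118, 0.398 and 4.25 CPM in OE, and OAS2 at 26.9, 0.144 and 2.75 CPM in NC and 28.4, 0 and 5.53 CPM in OE. VIM, which encodes vimentin, stood at 4126, 2141 and 1092 CPM in NC and 4619, 2505 and 980.0 CPM in OE, and KRT8 at 1265, 807 and 298 CPM in NC and 1371, 637 and 230.3 CPM in OE. HSPA1B stood at 39.9, 19.1 and 17.0 CPM in NC and 207, 13.9 and 18.2 CPM in OE. OE replicate 1 held the most MIR193BHG and the most TP53 of the 6 libraries, 39.5 and 110.7 CPM, and with 3 OE libraries no relation between them was tested.

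The tests of TP53 without OE replicate 1 and on the p53 target list, the tests of each list on its own, and the length and GC correction were chosen after the values were seen. The first pattern is the 7 lists that passed with the preset correlation, of which 5 were still called in the same direction after the length and GC correction and 4 without OE replicate 1. At the preset correlation, the length and GC trend is argued against as the whole cause for those 5. Their corrected medians were 0.139 for G2/M and mitosis, −0.196 for NF-kB, −0.196 for integrated stress, −0.0714 for oxidative phosphorylation and 0.246 for mitochondrial genes. With an estimated correlation the corrected adjusted p was 0.821 for each of the 5. The correction used the length of all annotated exons of a gene joined, which can exceed that of its transcripts. A remaining length trend is therefore not excluded. It stays open for the immediate early genes, whose call ended as the median went from −0.23 (quartiles −0.46 to −0.10) to −0.135 (−0.36 to −0.015), and for the ribosomal proteins, whose median was −0.062 (−0.17 to −0.012) before and −0.0688 (−0.13 to 0.0071) after while the mean t statistic went from −0.38 to −0.30. OE replicate 1 alone was tested in pairs 2 and 3 with the block and the preset correlation, which leaves NC replicate 1 out too. At that correlation it is argued against for G2/M and mitosis (mean log2 difference 0.190, camera adjusted p = 0.0074), ribosomal proteins (−0.147, 0.0197) and oxidative phosphorylation (−0.157, 0.0197). The estimated correlations of these lists with all 6 libraries were higher, at 0.50, 0.37 and 0.63, and none of them passed there. The NF-kB list was hardly shifted in pairs 2 and 3 (−0.0166, camera adjusted p = 0.910), so its shift lay in pair 1. With both libraries of pair 1 left out, this cannot tell OE replicate 1 from NC replicate 1, without which the NF-kB call was also lost. OE replicate 1 alone therefore stays open for NF-kB, and likewise for integrated stress (−0.0965), immediate early (−0.164) and mitochondrial genes (0.134). Leaving out OE replicate 1 only, without a block, gave medians of −0.0125 for mitosis and −0.246 for NF-kB. Those medians point the other way, in a fit that leaves NC replicate 1 unpaired. No test separate from the group comparison was run for a response to MIR193BHG, which stays open, and 0 lists passed with an estimated correlation.

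The second pattern is the higher TP53 level without a matching shift of p53 targets. A joint rise with the overlapping gene WRAP53 is argued against, since its log2 difference lay below that of TP53 by more than 2 standard errors (−0.71, SE 0.31). Reads moved from WRAP53 to TP53 would raise TP53 and lower WRAP53, which this test cannot tell from a rise of TP53 alone. From NC to OE, TP53 counts went from 808 to 1521 in pair 1 and from 704 to 1134 in pair 2. Those of WRAP53 went from 1508 to 1436 and from 1133 to 1209, so WRAP53 did not lose the reads that TP53 gained. This argues against such a move as the whole cause in pairs 1 and 2. In pair 3 (TP53 789 to 830, WRAP53 1419 to 1103) that explanation stays open. Without OE replicate 1 the log2 difference was 0.35 (SE 0.19), 55.3% of its value, with both remaining OE libraries above all NC libraries. This met the bounds set for arguing against OE replicate 1 alone. Those bounds were set after the values were seen, and 0.35 lies within 2 standard errors of no difference. OE replicate 1 alone therefore stays open. Higher p53 activity could not be settled, since the mean log2 difference of the target list over the 3 pairs was −0.063 with a 95% interval of −0.41 to 0.28. This list reads RNA, so a change of p53 protein that left these targets alone would not be seen.

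The third pattern is 26 genes with under 0.2 CPM in some library and at least 5 CPM in another, among them UPK3BL1, RPS10-NUDT3 and RPL17-C18orf32. RPS10-NUDT3 stood at 2.01, 0 and 67.8 CPM in NC and 45.1, 34.4 and 47.7 CPM in OE. Of the 26, 20 (76.9%) overlapped another gene, or were pseudogenes or readthrough genes, against 56.2% of the other tested genes, an odds ratio of 2.60 (95% interval 1.01 to 7.92, Fisher's exact p = 0.0459). This is in line with reads moving between overlapping annotations, which may also bear on UPK3BL1, called by DESeq2. In 2 of the 26 (7.69%, 95% interval 0.946% to 25.1%) the groups did not overlap, where chance would give 10% for unpaired libraries. An effect of MIR193BHG on a few of them stays open.

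The 10 splits of the 6 libraries are too few for a share under 0.05, and the numbers of splits that reach the real value include the real split itself. As many lists as the real 7 were called in 5 splits, with 10 in the highest other, and with the block the real split called 10 lists and the other splits that part all 3 pairs 5, 6 and 2. As many genes as the real 1 were called in 4 splits, with 2 in the highest other, where with the block the real split called 0 and the others that part all 3 pairs 2, 2 and 0. In 8 splits at least as many genes as the real 169 lay past the study's threshold, with 2230 in the highest other. That split, NC replicates 1 and 2 with OE replicate 1 against the rest, and that of NC replicate 1 with OE replicates 1 and 2, at 2094, keep replicates 1 and 3 apart and point to a structure of the samples by replicate number. With the block, the real split placed 425 genes past the study's threshold, and the other splits that part all 3 pairs placed 319, 317 and 549.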
